A study of Arabidopsis thaliana with 24 samples.

How the data were processed

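Seedlings of Arabidopsis thaliana were sampled in 8 groups of 3 samples each, 24 libraries in all. The groups combined 2 genotypes, 2 temperatures and 2 time sets. The genotypes were wild-type Col-0 (WT) and sig5-3 (SALK_141383C), a T-DNA insertion line of the nuclear gene SIG5, per the series title. SIG5 encodes a sigma factor that directs the plastid-encoded RNA polymerase of chloroplasts to promoters. Per the labels' protocols, plants were grown in a photoperiod of 12 h, moved to continuous light for 24 h, and then either chilled at 4 °C or left at 19 °C. Each sample pooled 10 seedlings after 11 days of growth, and the 3 samples of a group were independent replicates. Zeitgeber time (ZT) counts hours from dawn. Chilling began at ZT27 and lasted 5 h in the first time set, and began at ZT45 and lasted 3 h in the second. Start time and length of chilling therefore differ together, and their effects cannot be told apart. Below, ZT27 and ZT45 name the time sets by the start of treatment, also at 19 °C, and not by the hour of sampling.

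Per the labels' protocols, libraries were made with a stranded kit from polyadenylated RNA. Per the submitters' processing notes, the tools included STAR 2.4.1d and Partek 6.6, and the series' design text calls the genome TAIR11. How reads were assigned to genes and scaled is not given in the sources used here. The deposited values are a signal, a normalized read abundance per gene that the authors scaled for each library and did not divide by gene length. The library totals ran from 790711 to 1092052 and most values were not whole, so the values are not raw counts. Among values under 30, between 88.8% and 91.4% per library were whole multiples of a step common to all genes of that library, within a tolerance of 0.05 steps. Taking that step as the worth of 1 read, 1 read was worth 0.02292 to 0.03717. The libraries held an estimated 21274958 to 36440701 reads on genes with values, and reads on genes without values are not in this estimate. The other values were not multiples of the step, so whole reads were not rebuilt. A count of 3 reads, the limit that a count of 0 allows, corresponds to 0.0688 to 0.1115 depending on the library. That limit covers counting error only.

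Values were present for 17952 of 37336 genes, of which 17515 are protein coding. The other 19384 had no number in any library, and the lowest mean among the genes with values was 1.01. All 133 plastid-encoded and all 152 mitochondrion-encoded genes were among those without values and were not analysed here, so the plastid transcripts on which SIG5 acts were not measured. The planned share of organelle-encoded transcripts was not computed for the same reason. Names, gene types and coordinates were taken from the NCBI RefSeq annotation of TAIR10.1, which matched all 17952 genes with values. Coordinates are given in TAIR10.1 only.

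The tests were planned as a count test on raw counts. The values turned out to be normalized, so the test that fits such values was used in its place. Values were transformed to log2(value + 0.5), and limma 3.58.1 in R 4.3.3 was fitted to all 24 libraries with the 8 group means as coefficients, 16 residual degrees of freedom, and empirical Bayes moderation with a mean trend and robust settings. P-values were adjusted over the 17952 genes by the Benjamini-Hochberg method in each comparison. A gene passed at an adjusted p under 0.05. It was called when its log2 fold change also exceeded 1.5 in size, the threshold given in the series' design text. All fold changes are on the log2(value + 0.5) scale, which understates changes of genes at low values. Errors of log2 fold changes are standard errors (SE) from the fit, which for a gene are the same in every comparison of 2 groups of 3, and errors of group means are standard deviations (SD) with n = 3. Adjusted p-values of genes come from limma throughout. No gene was filtered out beyond the genes without values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.

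The comparisons, the called threshold, the gene lists and the rule for named genes were fixed before the data were examined. Comparisons were chilling in each genotype and time set, sig5-3 against WT in each of the 4 conditions and averaged over them, the difference of the chilling responses between genotypes in each time set, the difference of the WT chilling response between time sets, and the time sets of WT at 19 °C. Named genes were SIG5 and the 6 sigma factor genes throughout. For chilling and time comparisons they were the 8 largest increases and 8 largest decreases among called genes with a mean of at least 10 and no overlap between the samples compared. For genotype comparisons all called genes were named, and for differences of responses all called genes or the 5 largest each way. From each list, up to 4 members with the smallest adjusted p and members moving against the rest could be named.

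Of 25 gene lists, 19 had members with values. They were the sigma factors (6 genes with values), cold-induced transcription factors (13 of 15), COR genes (15), morning-phased (12) and evening-phased (12) clock genes, nuclear proteins of the plastid RNA polymerase complex (14), nuclear light-harvesting genes (18), chlorophyll biosynthesis (11 of 12), HY5-associated light response (11), flavonoid and anthocyanin (12 of 13), abscisic acid and osmotic response (10 of 12), heat shock proteins (4 of 11), touch and early stress (8 of 9), starch degradation (13), raffinose pathway (3 of 5), auxin and elongation growth (10 of 16), cytosolic ribosomal proteins (13 of 19), salicylic acid defence (3) and root markers (5 of 10). GOLS3 belongs to both the COR and the raffinose list. The ribosomal list was built from annotated product names that give the ribosomal subunit, so it holds only part of the family. For example, AT3G11120 and AT3G08520, annotated as ribosomal protein L41 family, are outside it. The polymerase list also holds RPOTP and RPOTMP, phage-type polymerase genes whose products are not proteins of that complex. Lists of plastid-encoded and mitochondrion-encoded genes and of seed storage genes had no member with values and were not analysed here. Each list was tested in each comparison with camera of limma at a preset correlation between genes of 0.01, which compares the list with all other genes. The 247 list tests were adjusted together, and a list was called at an adjusted p under 0.05. The number of members that passed was also counted with p-values adjusted over the list alone. Where the chilling results give no such count, it differed from the count over all genes by at most 3. The tests were repeated with an estimated correlation between genes, and with fry, which asks whether a list's genes moved one way on balance.

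The scripts were tested on simulated values for the 17952 genes with 50 genes shifted at each size. For chilling of WT at ZT27, 0% of genes shifted by a log2 of 1 were called, as the threshold requires, and 98% passed. At a shift of 2, 94% were called, and at 3 and at 4, 100%. For the difference of the chilling responses between genotypes at ZT27, 88% of genes shifted by 1 passed, and 90% of those shifted by 2 were called. Among unshifted genes, 16 passed for chilling of WT at ZT27 and 8 for that difference, and 0 were called. The simulation gave each gene the same spread in all groups and had no library that lay apart from its group. It therefore does not give the power of the real test of that difference. In simulated comparisons without any change 0 genes were called by limma and 4.61% to 5.19% had an unadjusted p under 0.05.

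Alternatives planned before the data were examined were calling by adjusted p alone, fitting only the groups compared, a replicate block, leaving out each replicate, and the list tests named above. The planned median-ratio normalization was run on the deposited values after their unit was known. A count model, a fit without a low-count filter and a fit without organelle genes were not run, because they need counts or genes that had no values. Alternatives chosen after seeing the data were pseudocounts of 0.1 and 2, a minimum mean of 5, array weights, and leaving out 1 sig5-3 library that lay apart from its group. Libraries within a group were compared pairwise, and the smallest chi-square per gene between 2 libraries of a group was 2.66, where sampling noise alone gives about 1.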

Results

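Messenger RNA abundance was measured in 24 libraries of Arabidopsis seedlings, 3 for each of 8 groups: WT and sig5-3, at 4 °C or 19 °C, in the ZT27 set (5 h of chilling) and the ZT45 set (3 h of chilling). The estimated number of reads on the genes with values was 21274958 to 36440701 per library. In a principal component analysis, component 1 held 46.2% of the variance and component 2 held 37.4%, and together they separated the 4 combinations of temperature and time set, with both genotypes side by side in each. Pearson correlations between libraries of a group were at least 0.980. One library lay apart: replicate 1 of sig5-3 at 4 °C in the ZT27 set deviated from its group mean by a root mean square of 0.263 on the log2 scale, against 0.082 to 0.17 in the other 23. It was kept, and counts without it are given beside the results it changed most. All groups share one estimate of the error, so leaving it out also changed comparisons that do not include it, and 7788 genes passed at an adjusted p under 0.05 against 6396 for chilling in WT at ZT45.

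SIG5 (AT5G24120; chromosome 5, 8157151 to 8160343, minus strand, TAIR10.1), the gene disrupted in sig5-3, was measured first in every group. In WT at ZT27 its mean was 9.15 ± 1.58 (SD, n = 3) at 19 °C and 92.8 ± 3.66 at 4 °C. At ZT45 the WT means were 46.1 ± 4.61 at 19 °C and 142 ± 7.38 at 4 °C. In sig5-3 the means were 1.3 ± 0.653 and 19.7 ± 3.25 at ZT27 and 9.45 ± 0.863 and 32 ± 5.61 at ZT45, in the same order of temperatures. SIG5 transcript in sig5-3 was thus 14.2%, 21.3%, 20.5% and 22.6% of the WT mean in the 4 conditions, and each of the 12 sig5-3 libraries lay below each WT library of its condition. By limma, the log2 fold change of sig5-3 against WT was −2.47 (adjusted p = 4.5e-07) at 19 °C and −2.22 (adjusted p = 2.8e-06) at 4 °C at ZT27. With only the groups compared in the fit, the 19 °C value at ZT27 kept its size but not its call (adjusted p = 0.0639). At ZT45 it was −2.23 (adjusted p = 2.6e-06) at 19 °C and −2.14 (adjusted p = 4.8e-06) at 4 °C, with an SE of 0.19 each time. The transcript was still detected, and whether it spans the insertion was not analysed here.

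Chilling raised SIG5 in both genotypes. The log2 fold change in WT was 3.29 ± 0.19 (SE; adjusted p = 7.9e-12) at ZT27 and 1.61 ± 0.19 (adjusted p = 1e-06) at ZT45. In sig5-3 it was 3.54 ± 0.19 (adjusted p = 2.1e-12) and 1.69 ± 0.19 (adjusted p = 5.2e-07). As ratios of group means, SIG5 was 10.1 times as high at 4 °C as at 19 °C in WT at ZT27 and 3.07 times at ZT45, and 15.2 times and 3.38 times in sig5-3. The difference between genotypes in this response was 0.25 ± 0.26 at ZT27 (adjusted p = 0.72) and 0.08 ± 0.26 at ZT45 (adjusted p = 1), not larger than its error, and with a pseudocount of 2 it turned to −0.37 and −0.03.

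**Figure D1:**
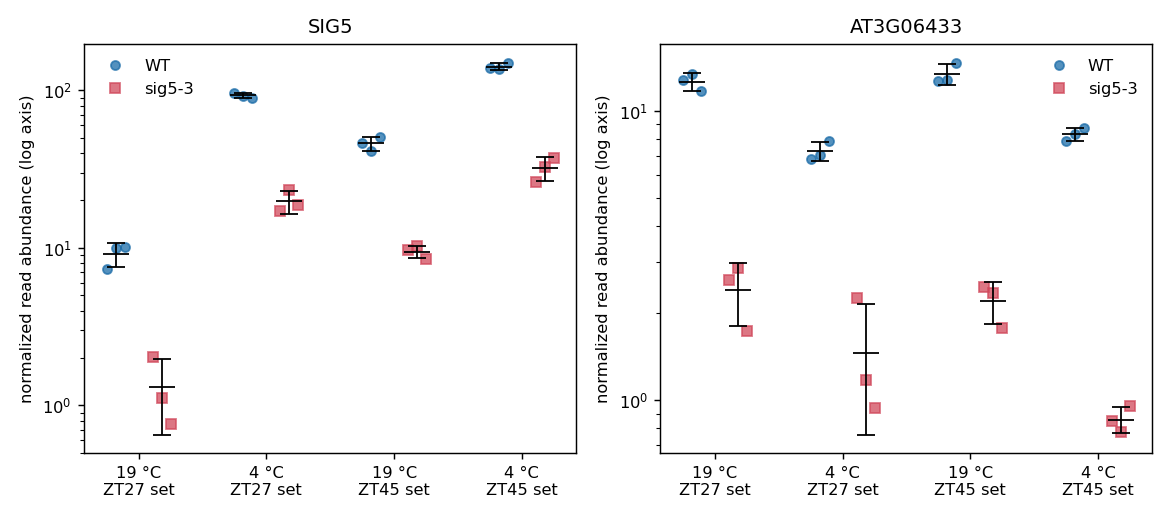
Normalized abundance (log axis) of SIG5 and of AT3G06433 in each library by genotype, temperature and time set, with the mean ± SD of 3 libraries per group. Group means of SIG5 in sig5-3 lay between 14.2% and 22.6% of the WT mean and single libraries between 8.33% and 26.3%, and SIG5 rose with chilling in both genotypes.

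The next question was which transcripts responded to chilling in WT. After 5 h at 4 °C from ZT27, large increases were found for the genes that follow. GOLS3, a galactinol synthase of the raffinose pathway, rose from 2.21 ± 0.0442 to 445 ± 9.18 (SD, n = 3; log2 fold change 7.36 ± 0.15). RD29A, a classical cold and drought response gene, rose from 74.7 ± 3.68 to 3350 ± 80.4 (5.48 ± 0.11), and ADH1, alcohol dehydrogenase, from 6.52 ± 0.525 to 368 ± 6.7 (5.72 ± 0.12). The plastid glucose 6-phosphate transporter GPT2 rose by 6.15 ± 0.19 and the early light-induced protein ELIP2 by 5.4 ± 0.2. AT1G04570, a predicted major facilitator transporter, had the largest increase of the named genes, 7.85 ± 0.09, from 0.764 ± 0.201 to 288 ± 7.07. The PB1 domain gene AT1G70640 rose by 6.08 ± 0.14, and the noncoding RNA AT4G06665 by 6.07 ± 1.09 (adjusted p = 0.00014), with a residual SD of 1.35 against a median of 0.12 over all genes. Among the decreases, BT2, which encodes a BTB and TAZ domain protein, fell from a mean of 93.1 to 2.94 ± 0.591 (−4.77 ± 0.16), and NCED4, a carotenoid cleavage dioxygenase, from 64.1 ± 9.81 to 5.61 ± 0.16 (−3.39 ± 0.09). The Kelch repeat F-box gene AT1G23390 fell (−4.26 ± 0.14), as did the DnaJ-type chaperone gene J8 (−3.29 ± 0.17), AT1G18000 (−4.18 ± 0.18), AT5G19190 (−3.52 ± 0.15), AT3G62550 (−3.29 ± 0.11) and AT5G11070 (−3.26 ± 0.11). In all, limma called 833 genes, 573 higher and 260 lower, which is 4.64% of those tested, and 10135 genes passed at an adjusted p under 0.05 without the fold threshold.

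Among the cold-response lists in WT at ZT27, all 13 cold-induced transcription factors rose, and all 13 adjusted over the list alone (median 2.27, camera adjusted p = 7.4e-10, adjusted p = 0.069 with an estimated correlation). They included CBF2 (3.8 ± 0.12), a master regulator of cold acclimation, DEAR1 (3.51 ± 0.16) and the zinc finger genes ZAT10 (3.69 ± 0.2) and ZAT12 (2.27 ± 0.15). All 15 COR genes, a list of cold-regulated genes, rose, 15 adjusted over the list alone, with a median of 2.58 (adjusted p = 5.8e-14, adjusted p = 0.026 with an estimated correlation). Examples besides RD29A were LTI30 (5.28 ± 0.17), COR15A (4.69 ± 0.17) and ERD10 (4.1 ± 0.08), while FAD8, a fatty acid desaturase, rose by 0.22 ± 0.07. All 3 raffinose pathway genes rose (median 2.82, adjusted p = 0.00016, adjusted p = 0.08 with an estimated correlation), with RS5, raffinose synthase, at 2.82 ± 0.1 and GOLS1 at 1.65 ± 0.11. Of 10 abscisic acid and osmotic response genes 8 rose, 8 adjusted over the list alone (median 0.92, adjusted p = 0.00025, adjusted p = 0.091 with an estimated correlation). NCED3, which makes the abscisic acid precursor, rose by 2.3 ± 0.14 and RD26 by 2.06 ± 0.18, while RAB18 was at −0.24 ± 0.17.

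Clock and light lists also moved in WT at ZT27. All 12 morning-phased clock genes rose, 12 adjusted over the list alone (median 1.82, adjusted p = 1.9e-09, adjusted p = 0.19 with an estimated correlation). Among them were CCA1 (3.58 ± 0.15), LHY (3.22 ± 0.12), PRR9 (3.47 ± 0.23) and RVE8 (2.37 ± 0.14). Of 12 evening-phased genes 7 rose and 4 fell, with the same counts adjusted over the list alone (median 0.59, adjusted p = 0.052). PRR5 (2.58 ± 0.1), GI (2.25 ± 0.11) and FKF1 (2.01 ± 0.1) rose, and CAT3 (−1.08 ± 0.11), PRR3 (−0.64 ± 0.11), BOA (−0.45 ± 0.15) and ELF3 (−0.3 ± 0.06) fell. All 12 flavonoid and anthocyanin genes rose, 12 adjusted over the list alone (median 2.02, adjusted p = 1.6e-08, adjusted p = 0.08 with an estimated correlation). They included F3H (3.2 ± 0.14), MYB111 (2.74 ± 0.13) and CHS (2.46 ± 0.11), chalcone synthase at the entry of the pathway. Of 11 HY5-associated light response genes 9 rose and 2 fell (median 1.23, adjusted p = 4.7e-05, adjusted p = 0.075 with an estimated correlation). ELIP1 rose by 4.72 ± 0.12, HYH by 2.65 ± 0.16 and HY5, the light-signalling transcription factor, by 1.07 ± 0.09, whereas the photoreceptor gene CRY1 (−0.71 ± 0.06) and BBX21 (−0.32 ± 0.08) fell.

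Lists of plastid function were also tested in WT at ZT27. Of 18 nuclear light-harvesting genes 8 rose and 10 did not pass, 8 adjusted over the list alone (median 0.22, adjusted p = 0.03, adjusted p = 0.66 with an estimated correlation). In the fit without the library that lay apart, which enters this comparison only through the shared error, 12 rose. LHCB1.1 (1.04 ± 0.1) and LHCB2.1 (0.97 ± 0.1) rose most, but the LHCB1 and LHCB2 copies are nearly identical and the split of reads among them is uncertain. Of 14 nuclear proteins of the plastid RNA polymerase complex 10 fell and 1 rose, and 11 and 1 adjusted over the list alone (median −0.24, adjusted p = 0.0046, adjusted p = 0.46 with an estimated correlation). PAP8 (−0.59 ± 0.06) and PAP5 (−0.57 ± 0.08) fell. The member that rose was RPOTMP (0.33 ± 0.08), a phage-type polymerase gene whose product is not a protein of that complex. Of 11 chlorophyll biosynthesis genes 5 rose and 4 fell (median 0.07, adjusted p = 0.37). HEMA1, which acts at the start of tetrapyrrole synthesis, rose by 1.41 ± 0.08 and GUN4 by 1.03 ± 0.08, and the protochlorophyllide reductase gene PORB fell (−0.96 ± 0.1). Among the sigma factor genes other than SIG5, SIG1 (0.99 ± 0.1) and SIG3 (0.11 ± 0.05) rose, SIG4 (−1.23 ± 0.06) and SIG2 (−0.25 ± 0.05) fell, and SIG6 was at 0.09 ± 0.05. The list of 6 was not called (adjusted p = 0.59).

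Of the other lists in WT at ZT27, 6 of 10 auxin and elongation growth genes fell and 2 rose (median −0.66, adjusted p = 0.031, adjusted p = 0.4 with an estimated correlation). The expansin genes EXPA8 (−3.14 ± 0.13) and EXPA1 (−2.24 ± 0.07), which loosen cell walls, fell most, and ATHB2 (0.59 ± 0.12) and HAT2 (0.55 ± 0.14) rose. The remaining 6 lists were not called. Of 8 touch and early stress genes 6 rose, with CML38 at 2.32 ± 0.51 and WRKY33 at 2.23 ± 0.25, and WRKY53 (−0.49 ± 0.19) fell (adjusted p = 0.072). Of 13 starch degradation genes 7 rose and 3 fell (adjusted p = 0.48): BAM3, a plastid beta-amylase, rose by 3.61 ± 0.08, and DPE1 (−0.85 ± 0.07), PHS1 (−0.79 ± 0.07) and PWD (−0.31 ± 0.08) fell. Of 4 heat shock genes HSP70 (0.41 ± 0.17) and HSP18.2 (0.37 ± 0.1) rose and HSP101 (−0.68 ± 0.14) fell (adjusted p = 0.81). Of 13 ribosomal protein genes only AT5G47940 (−0.55 ± 0.13) and AT1G57540 (−0.36 ± 0.09) passed, both lower (median 0, adjusted p = 0.75). Of 3 salicylic acid defence genes PR5 rose by 1.62 ± 0.2 (adjusted p = 0.2 for the list). Of 5 root markers NRT2.1 rose by 0.51 ± 0.21 and SCR fell (−0.43 ± 0.07), with the median at 0.26 and the mean at 0.12 while the test leaned down (adjusted p = 0.99).

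**Figure D2:**
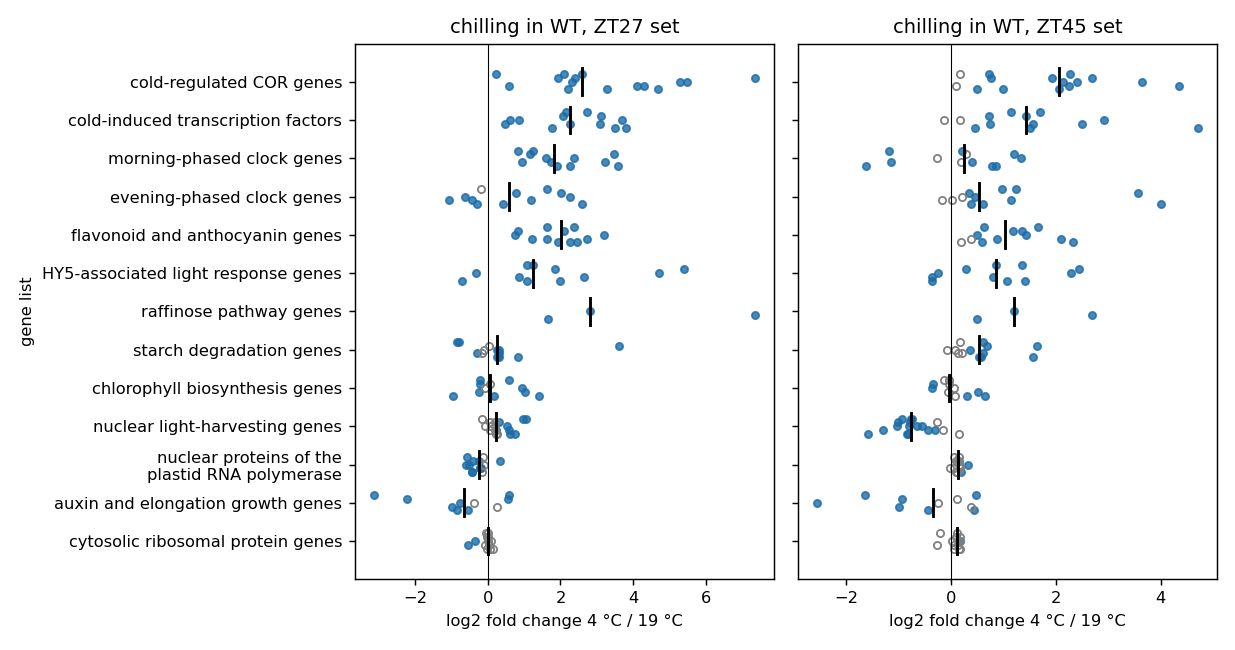
Log2 fold change (4 °C against 19 °C) in WT of each member of 13 gene lists, at ZT27 and ZT45. Filled points passed at an adjusted p under 0.05, open points did not, and bars mark the median, which for the light-harvesting genes was 0.22 at ZT27 and −0.77 at ZT45.

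In WT at ZT45, chilling lasted 3 h. CBF2 rose from 0.287 ± 0.0842 to 20.3 ± 3.54 (SD, n = 3; log2 fold change 4.72 ± 0.12). COR15B, a chloroplast cold-protective protein, rose from 3.2 ± 1.15 to 72.5 ± 3.96 (4.35 ± 0.19), RD29A from 15.4 ± 2.65 to 196 ± 18 (3.64 ± 0.11), and the clock gene PRR5 from 2.01 ± 0.295 to 39.6 ± 3.9 (4 ± 0.1). AT1G11210 rose by 4.93 ± 0.12 and AT1G04570 by 4.9 ± 0.09, and GPT2 (3.88 ± 0.19) and BBX29 (3.88 ± 0.12) were the other 2 of the 8 largest increases. PIF4, a growth-promoting transcription factor, fell from 6.23 ± 0.949 to 0.643 ± 0.189 (−2.56 ± 0.12), and the ERF-type factor AT5G61590 from 23.5 ± 2.94 to 1.27 ± 0.121 (−3.76 ± 0.1). Falls were also found for AT5G19190 (−3.59 ± 0.15), BT2 (−3.36 ± 0.16), the noncoding RNA AT3G09275 (−2.79 ± 0.34), AT1G23390 (−2.58 ± 0.14), AT5G11070 (−2.57 ± 0.11) and J8 (−2.57 ± 0.17). By limma 228 genes were called, 139 higher and 89 lower, and 6396 passed without the fold threshold.

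At ZT45 in WT, 11 of 13 cold-induced transcription factors rose, 11 adjusted over the list alone (median 1.43, adjusted p = 4e-09, adjusted p = 0.075 with an estimated correlation), and MYB73 and CRF2 were at −0.13 ± 0.11 and 0.17 ± 0.1. Of 15 COR genes 13 rose, 14 adjusted over the list alone (median 2.06, adjusted p = 3.3e-14, adjusted p = 0.026 with an estimated correlation), and FAD8 and COR413IM2 did not pass. All 3 raffinose genes rose (adjusted p = 0.00068, adjusted p = 0.1 with an estimated correlation), and 8 of 10 abscisic acid and osmotic genes (median 0.54, adjusted p = 9.6e-05, adjusted p = 0.08 with an estimated correlation). Of 12 evening-phased clock genes 9 rose, 9 adjusted over the list alone (median 0.54, adjusted p = 7.1e-07, adjusted p = 0.026 with an estimated correlation), led by PRR5, FKF1 (3.57 ± 0.1) and GRP7 (1.24 ± 0.13). Of 12 morning-phased genes 6 rose, such as CCA1 (0.85 ± 0.15), and 3 fell, LNK1 (−1.62 ± 0.13), PRR7 (−1.19 ± 0.07) and LNK2 (−1.14 ± 0.11), and the list was not called (adjusted p = 0.82). Of 18 light-harvesting genes 15 fell, 16 adjusted over the list alone (median −0.77, adjusted p = 5.3e-11, adjusted p = 0.24 with an estimated correlation), with LHCB2.2 at −1.58 ± 0.09, LHCB2.3 at −1.3 ± 0.11 and LHCB3 at −1.03 ± 0.09.

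Flavonoid genes rose at ZT45 in 10 of 12 cases, 10 adjusted over the list alone (median 1.03, adjusted p = 9.7e-08, adjusted p = 0.09 with an estimated correlation). MYB12 was at 2.32 ± 0.15, while DFR (0.19 ± 0.23) and LDOX (0.37 ± 0.19), late anthocyanin enzymes, did not pass. Of 11 HY5-associated genes 8 rose, with HY5 at 1.41 ± 0.09, and CRY1, BBX20 and BBX21 fell (median 0.86, adjusted p = 0.00049, adjusted p = 0.091 with an estimated correlation). Of 13 starch degradation genes 8 rose, 8 adjusted over the list alone (median 0.54, adjusted p = 2.1e-05, adjusted p = 0.25 with an estimated correlation), with BAM3 at 1.63 ± 0.08 and PHS2 at 1.56 ± 0.1. The sigma factor list was called (adjusted p = 0.03, adjusted p = 0.19 with an estimated correlation), with SIG1 (0.31 ± 0.1) and SIG6 (0.31 ± 0.05) higher beside SIG5. Of 10 auxin and growth genes 5 fell and 2 rose (adjusted p = 0.026, adjusted p = 0.38 with an estimated correlation), and EXPA11 rose by 0.44 ± 0.09. The other 7 lists were not called. PAP8 (0.33 ± 0.06), FSD2 (0.15 ± 0.05) and MURE (0.19 ± 0.07) rose among the 14 polymerase-associated genes, of which 1 passed adjusted over the list alone and 6 over all genes without the library that lay apart. Of 11 chlorophyll genes 3 rose, PORB by 0.65 ± 0.1, and 2 fell, with a median of −0.04 and a mean of 0.06. HSP70 (−0.71 ± 0.17) and HSP101 (−0.72 ± 0.14) fell, WRKY33 rose by 1.2 ± 0.25 as the 1 touch gene that passed, the ribosomal gene AT4G00810 rose by 0.17 ± 0.06, and 4 of 5 root markers rose. Without the library that lay apart 2 touch genes rose, and 4 ribosomal genes rose and 1 fell. PR5 rose by 0.79 ± 0.2, and the salicylic acid list had a median of −0.23, a mean of 0.09 and an upward test (adjusted p = 0.8).

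In sig5-3, chilling at ZT27 changed GOLS3 from 2.49 ± 0.355 to 563 ± 104 (SD, n = 3; log2 fold change 7.55 ± 0.15) and RD29A from 74.8 ± 7.15 to 4030 ± 728 (5.73 ± 0.11). AT1G04570, GPT2, AT1G70640, ADH1 and ELIP2 rose by 8.01, 6.66, 6.6, 6.14 and 5.93, as they did in WT, and AT5G17460 rose by 5.43 ± 0.1. The falls were BT2 (−5.2 ± 0.16), AT1G23390 (−4.83), J8 (−4.11), AT5G19190 (−3.95), AT1G18000 (−3.9), AT3G62550 (−3.36), AT3G26510 (−3.25 ± 0.11) and MIOX2, an inositol oxygenase (−3.23 ± 0.31). At ZT45 CBF2 rose from 0.297 ± 0.0309 to 28.9 ± 4.11 (5.2 ± 0.12), followed by AT1G04570 (4.79), AT1G11210 (4.65), the zinc finger gene ZAT6 (4.14 ± 0.19), COR15B (4.06), BBX29 (3.98), PRR5 (3.97) and FKF1 (3.71 ± 0.1). BBX15 fell from 111 ± 5.59 to 21.8 ± 2.81 (−2.34 ± 0.11), beside AT5G61590 (−4.02), AT3G09275 (−3.56 ± 0.34), BT2 (−3.26), AT5G19190 (−3.24), AT1G18000 (−2.44), AT5G11070 (−2.41) and PIF4 (−2.24, and not called with a pseudocount of 2, at −1.47). By limma 899 genes were called at ZT27, 600 higher and 299 lower, and 257 at ZT45, 174 higher and 83 lower. Without the library that lay apart, 918 genes were called at ZT27, of which 841 were among the 899.

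The same 13 cold transcription factors, 15 COR genes, 12 morning clock genes, 12 flavonoid genes and 3 raffinose genes rose in sig5-3 at ZT27 as in WT, with camera adjusted p = 1.9e-09, 1.2e-13, 1.9e-08, 2.2e-09 and 2e-04. With an estimated correlation the COR list kept its call (adjusted p = 0.026), and the others had adjusted p = 0.075, adjusted p = 0.19, adjusted p = 0.075 and adjusted p = 0.08 with an estimated correlation. HY5-associated genes (9 rose, 2 fell, adjusted p = 7e-05) and abscisic acid and osmotic genes (9 of 10 rose, adjusted p = 3.3e-05) were called too, each with adjusted p = 0.075 with an estimated correlation. Auxin and growth genes were called (7 fell, 1 rose, adjusted p = 0.015, adjusted p = 0.35 with an estimated correlation). So were the plastid polymerase proteins (8 fell, 1 rose, adjusted p = 0.032, adjusted p = 0.54 with an estimated correlation) and evening-phased genes (7 rose, 4 fell, adjusted p = 0.045, adjusted p = 0.27 with an estimated correlation). Of 18 light-harvesting genes 16 rose, 16 adjusted over the list alone (median 0.45, adjusted p = 0.00053, adjusted p = 0.53 with an estimated correlation). In the library that lay apart the median of this list stood 0.48 above the mean of the other libraries of its group, against −0.21 to 0.24 in 21 libraries of other groups, and without it 12 rose (median 0.26). The heat shock list stood 0.68 higher in that library and the morning clock list −0.57, against −0.18 to 0.22 and −0.21 to 0.31. SIG1 (0.86) and SIG4 (−0.85) moved in the same directions as in WT, SIG4 by less, though this difference between genotypes did not pass. SIG3 and SIG6 rose by 0.15 and 0.16, and SIG2, which fell in WT, was at −0.06. The lists of chlorophyll (5 rose, 1 fell), heat shock (2 and 1), touch (5 and 1), starch (6 and 3), ribosomal (3 and 2), salicylic acid (1 and 0), root (1 and 1) and sigma factor genes (4 and 1) were not called. Without that library 1 heat shock gene rose and 1 fell, and 2 ribosomal genes fell.

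At ZT45 in sig5-3, 13 of 15 COR genes (adjusted p = 1.9e-15) and 9 of 12 evening-phased genes (adjusted p = 2.6e-07) rose, both lists with adjusted p = 0.026 with an estimated correlation. Of 13 cold transcription factors 11 rose (adjusted p = 4.5e-11), and of 10 abscisic acid and osmotic genes 8 (adjusted p = 1.1e-06), both with adjusted p = 0.049 with an estimated correlation. Light-harvesting genes fell in 17 of 18 cases, 17 adjusted over the list alone (median −0.86, adjusted p = 7e-13, adjusted p = 0.2 with an estimated correlation). Also called were the HY5-associated genes (8 rose, 3 fell, adjusted p = 0.00023) and raffinose genes (3 rose, adjusted p = 0.00012), both with adjusted p = 0.08 with an estimated correlation. Of 12 flavonoid genes 8 rose (adjusted p = 6.9e-05, adjusted p = 0.2 with an estimated correlation). Of 13 starch degradation genes 8 rose (adjusted p = 2e-04, adjusted p = 0.31 with an estimated correlation). Touch genes (5 of 8 rose, adjusted p = 0.022, adjusted p = 0.46 with an estimated correlation) and sigma factors (4 rose, adjusted p = 0.026, adjusted p = 0.18 with an estimated correlation) completed the 11 called lists. SIG1, SIG3 and SIG6 rose by 0.33, 0.19 and 0.27. Morning-phased clock genes (7 rose, 3 fell), polymerase proteins (2 rose), chlorophyll (3 rose, 4 fell), heat shock (2 fell), auxin (3 rose, 5 fell), salicylic acid (1 rose) and root genes (3 rose) were not called, and ribosomal genes did not pass.

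Whether sig5-3 changed the chilling response was tested directly. The difference of the responses between genotypes was called by limma for 0 genes at ZT27, where 1782 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.127. At ZT45 it was called for 0 genes by limma, where 647 had an unadjusted p under 0.05 and the smallest adjusted p was 0.922. Simulated comparisons without any change gave 4.61% to 5.19% of the 17952 genes, and the 647 lies below that share and the 1782 above it. Without the library that lay apart 1 gene was called at ZT27, the noncoding RNA AT1G53233 (−1.92 ± 0.27, adjusted p = 0.016). Without replicate 2 of that group 3 were called, DREB26 (−1.58), AT3G02305 (−2.54) and RR5 (−1.53). These 4 genes were named after their values were seen. Across genes, log2 fold changes in WT and sig5-3 correlated with a Pearson r of 0.956 and a Spearman rho of 0.903 at ZT27, and 0.926 and 0.863 at ZT45. Genes are not independent replicates, and the 2 comparisons share no library. At ZT27, 750 genes were called in both genotypes, 515 up and 235 down, where independent lists would share 19.2 and 4.33, while 83 were called in WT alone and 149 in sig5-3 alone. At ZT45, 196 were called in both, 128 up and 68 down, against 1.35 and 0.411 for independent lists. Differences between genotypes of the genes called in 1 genotype alone were among those not called.

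**Figure D3:**
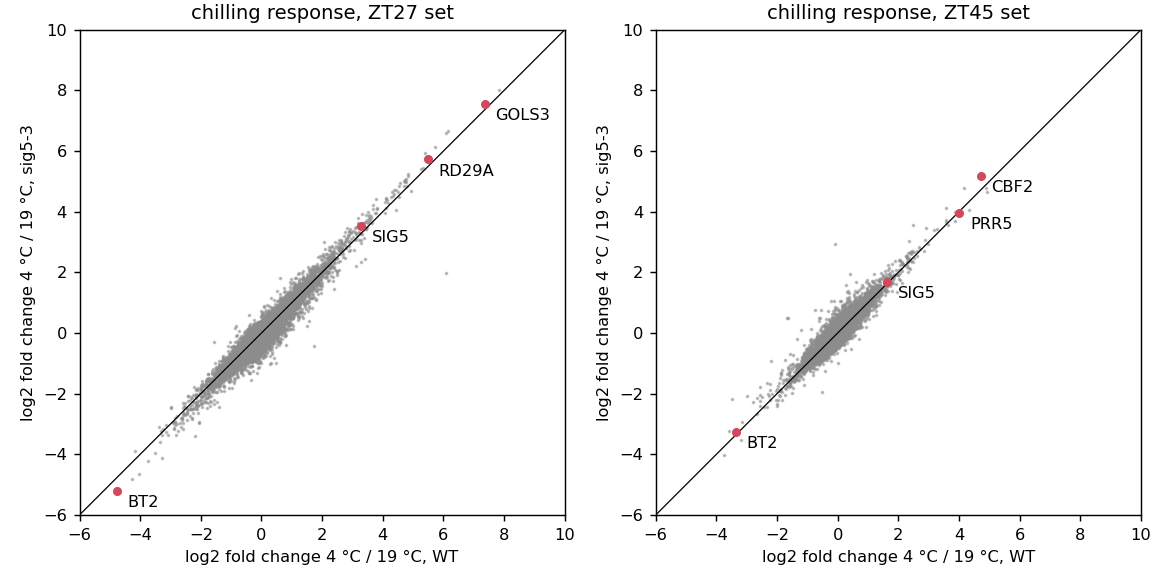
Log2 fold change with chilling in WT (x axis) against sig5-3 (y axis) for 17952 genes, at ZT27 and ZT45, with the line of equality and named genes. Pearson r was 0.956 at ZT27 and 0.926 at ZT45, and SIG5 rose in both genotypes.

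Among gene lists, the difference between genotypes at ZT27 was called for 6 lists, none with an estimated correlation. Flavonoid genes had a larger response in sig5-3 by a median of 0.34 (5 members adjusted over the list alone, adjusted p = 1.5e-05, adjusted p = 0.19 with an estimated correlation). Light-harvesting genes had a larger one by 0.22 (adjusted p = 0.00015, adjusted p = 0.51 with an estimated correlation), but by 0.04 without the library that lay apart. The abscisic acid (0.2), COR (0.19), HY5-associated (0.29) and sigma factor lists (0.13) had adjusted p = 0.2, adjusted p = 0.38, adjusted p = 0.25 and adjusted p = 0.19 with an estimated correlation. Without that library the medians were 0.33 for flavonoid, 0.15 for abscisic acid, 0.11 for COR, 0.25 for HY5-associated and 0.13 for sigma factor genes. At ZT45 10 lists were called, again none with an estimated correlation. Cold transcription factors (0.36, adjusted p = 5.1e-07, adjusted p = 0.091 with an estimated correlation) and touch genes (0.4, adjusted p = 1.2e-05, adjusted p = 0.19 with an estimated correlation) were higher. So were COR (0.17), abscisic acid (0.1) and morning clock genes (0.13). Flavonoid (−0.35), light-harvesting (−0.13), ribosomal (−0.12), starch (−0.13) and chlorophyll genes (−0.1) were lower, with adjusted p from 0.19 to 0.61 with an estimated correlation over these 8 lists. Flavonoid genes thus had median differences of opposite sign in the 2 sets, and whether the sets differ in this was not tested.

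The sig5-3 line was then compared with WT within each condition, and few genes were called. It is the only mutant line here, so effects of SIG5 cannot be told from other differences between that line and Col-0. Besides SIG5, AT3G06433 was lower in all 4 conditions. It is annotated as a transcribed pseudogene of the SWEET sugar transporter family (chromosome 3, 1958901 to 1962344, plus strand, TAIR10.1), so reads shared with related genes make its level uncertain. Its means in sig5-3 against WT were 2.4 ± 0.588 against 12.7 ± 0.884 (SD, n = 3) at 19 °C and 1.46 ± 0.697 against 7.26 ± 0.546 at 4 °C at ZT27. At ZT45 they were 2.2 ± 0.366 against 13.4 ± 1.13 and 0.859 ± 0.0897 against 8.31 ± 0.447. The log2 fold changes were −2.2, −2.04, −2.37 and −2.7, each ± 0.17, with adjusted p = 8.9e-08, 4e-07, 1.9e-08 and 1.3e-09, and the second was not called with only the groups compared in the fit (adjusted p = 0.119) or with a pseudocount of 2, where it was −1.44. AIG1, an immune-associated GTP-binding protein gene, was lower at 4 °C at ZT27, 3.84 ± 1.51 against 13 ± 3.97 (−1.66 ± 0.39, adjusted p = 0.022). Its call was lost when only the groups compared were fitted (adjusted p = 0.205), without WT replicate 1 (adjusted p = 0.105) or 3 (adjusted p = 0.0983), without the library that lay apart (−1.78, adjusted p = 0.0535), without sig5-3 replicate 2, where the fold change was −1.34, and with a pseudocount of 2, where it was −1.36. AT1G17960, annotated as a threonyl-tRNA synthetase, was lower at 19 °C at ZT45, 1.55 ± 0.378 against 8.83 ± 3.11 (−2.14 ± 0.23, adjusted p = 4.2e-05). At 4 °C in both time sets its sig5-3 libraries also lay below its WT libraries, without a call, and at 19 °C at ZT27 they overlapped. For AIG1 the same separation without a call was seen at 19 °C at ZT27, and at ZT45 its libraries overlapped at both temperatures. No other gene was called: 2 genes at 19 °C and 3 at 4 °C at ZT27, 3 at 19 °C and 2 at 4 °C at ZT45, all lower in sig5-3, where 1005, 4836, 1729 and 579 had an unadjusted p under 0.05. In simulated comparisons without any change 4.61% to 5.19% of the 17952 genes had such a p. The 579 lies below that share and the 1005 just above it. Leaving out WT replicate 2 at 4 °C at ZT27 gave 5 calls in that condition, leaving out sig5-3 replicate 2 gave 11 and replicate 3 gave 7.

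Without the fold threshold, 1336 genes passed between genotypes at 4 °C at ZT27, 822 higher and 514 lower in sig5-3, against 2 at 19 °C at ZT27, and 7 and 5 at 19 °C and 4 °C at ZT45. Without the library that lay apart 408 passed, 237 higher and 171 lower, against 9, 65 and 9 in the other conditions, and the 65 were 23 higher and 42 lower. Libraries of sig5-3 at 4 °C at ZT27 differed from the others of their group by a root mean square of 0.394, 0.255 and 0.244. Libraries of other groups reached at most 0.187, so the error shared by all groups may understate the spread here. With only the groups compared in the fit, 2463 genes had an unadjusted p under 0.05, against 4836. In the fit of all groups with every library, 13 of 18 light-harvesting genes were higher in sig5-3 at 4 °C at ZT27, 18 adjusted over the list alone (median 0.36, adjusted p = 2.7e-10, adjusted p = 0.25 with an estimated correlation). Medians of lists matched to these 18 genes for abundance centred on 0.25 and reached 0.34, against 0.36. Examples of the members were LHCB3 (0.42 ± 0.09) and LHCA1 (0.42 ± 0.12), but without the library that lay apart LHCB3 was the 1 that passed (median 0.19). Of 11 chlorophyll genes 6 were higher, 8 adjusted over the list alone (median 0.25, adjusted p = 5.5e-05, adjusted p = 0.19 with an estimated correlation), with GUN4 at 0.38 ± 0.08 and PORC at 0.34 ± 0.07, and 4 without that library. Of 12 flavonoid genes 5 were higher, 6 adjusted over the list alone (median 0.36, adjusted p = 2.4e-05, adjusted p = 0.19 with an estimated correlation), with UGT75C1 at 0.63 ± 0.13 and CHS at 0.52 ± 0.11, and 2 without it, though the median was then still 0.35. UGT75C1 was then at 0.54 (adjusted p = 0.0722) and CHS at 0.36 (adjusted p = 0.0607). FSD2 (0.22 ± 0.05) was the 1 of 14 polymerase proteins that passed, 6 adjusted over the list alone (adjusted p = 0.00029, adjusted p = 0.34 with an estimated correlation), and 3 passed without that library. COR413IM2 (0.26 ± 0.08) passed among COR genes (list adjusted p = 0.00095, adjusted p = 0.25 with an estimated correlation), but not without that library (0.17, adjusted p = 0.18), where 1 other COR gene passed. WRKY46, a stress-induced transcription factor, passed among touch genes (−1.17 ± 0.19, list adjusted p = 0.0044, adjusted p = 0.36 with an estimated correlation), but not without WT replicate 1 (−1.06, adjusted p = 0.0576) or with only the groups compared (adjusted p = 0.172). In the library that lay apart the touch list had a median of −0.47 against the others of its group. That is just beyond the −0.45 to 0.47 of 21 libraries in other groups. MEX1, a maltose exporter gene, passed among starch genes (0.3 ± 0.08, list adjusted p = 0.023, adjusted p = 0.53 with an estimated correlation), but not without that library (0.22, adjusted p = 0.104). So did 3 ribosomal genes (list adjusted p = 0.0024, adjusted p = 0.25 with an estimated correlation) that did not pass without the library. Outside the 8 called lists HSP90.1 (−1.02 ± 0.21) and EXPA11 (−0.44 ± 0.09) were lower and HY5 (0.33 ± 0.09), RUP2 (0.37 ± 0.11), SIG2 (0.26 ± 0.05) and SIG4 (0.44 ± 0.06) higher. Without that library HY5 (0.26, adjusted p = 0.0913) and RUP2 (0.19, adjusted p = 0.234) did not pass, and 3 heat shock and 2 auxin and growth genes were lower.

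Averaged over the 4 conditions, with 12 libraries of each genotype, SIG5 (−2.26 ± 0.09, adjusted p = 8.5e-12) and AT3G06433 (−2.33 ± 0.09, adjusted p = 8.3e-15) were the 2 called genes. Without the fold threshold 1147 passed, 724 higher and 423 lower, and 1660 did without the library that lay apart, 1080 higher and 580 lower. Members of photosynthesis lists were higher by small amounts. A trend with transcript abundance was tested for the light-harvesting genes only, and for the other lists it was not tested. Of 18 light-harvesting genes 15 were higher in sig5-3, 18 adjusted over the list alone (median 0.19, adjusted p = 3.1e-12, adjusted p = 0.2 with an estimated correlation), 15 without the library that lay apart and 13 with median-ratio scaling. LHCB2.3 was at 0.27 ± 0.06, LHCB1.1 at 0.25 ± 0.05 and LHCB3 at 0.22 ± 0.04. Of 11 chlorophyll genes 9 were higher, 9 adjusted over the list alone (median 0.15, adjusted p = 4.6e-09, adjusted p = 0.076 with an estimated correlation), 11 were without that library, and 8 were with median-ratio scaling. PORB was at 0.25 ± 0.05, PORC at 0.21 ± 0.04 and GUN5 at 0.2 ± 0.04. Of 14 polymerase proteins PAP1, PAP7 and PAP2 were higher by 0.14, 0.13 and 0.11, 10 adjusted over the list alone (adjusted p = 2.3e-05, adjusted p = 0.25 with an estimated correlation), 7 without that library and 1 with median-ratio scaling. Of 15 COR genes 4 were higher, COR15B (0.34 ± 0.1), COR15A (0.29 ± 0.09), RD29A (0.2 ± 0.05) and COR413-PM1 (0.15 ± 0.04), and 8 were higher adjusted over the list alone (adjusted p = 3.1e-05, adjusted p = 0.18 with an estimated correlation). They did not pass with median-ratio scaling, and COR15B did not without that library, at a similar size (0.3, adjusted p = 0.0696), where 5 of the list passed. Starch degradation genes (3 of 13 higher, 9 adjusted over the list alone, adjusted p = 3.3e-05) and flavonoid genes (CHS at 0.22 ± 0.06, 7 adjusted over the list alone, adjusted p = 0.00038) were also called, both with adjusted p = 0.25 with an estimated correlation. So were evening-phased genes (PRR5 at 0.18 ± 0.05, 2 higher adjusted over the list alone and 2 without that library, adjusted p = 0.013, adjusted p = 0.19 with an estimated correlation). Of 13 ribosomal genes 1 was higher, 4 adjusted over the list alone (adjusted p = 0.017, adjusted p = 0.35 with an estimated correlation).

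Lower in sig5-3 on average were HSP90.1 (−0.52 ± 0.1) and HSP70 (−0.28 ± 0.08) of the heat shock genes (adjusted p = 0.022, adjusted p = 0.27 with an estimated correlation). So was WRKY46 (−0.51 ± 0.09) of the touch genes (adjusted p = 0.00092, adjusted p = 0.28 with an estimated correlation). Outside the 10 called lists, BBX21 (−0.14 ± 0.04) and the root marker PYK10 (−0.21 ± 0.06) were lower and NCED3 (0.27 ± 0.07), P5CS1 (0.18 ± 0.05), SIG2 (0.15 ± 0.03), SIG4 (0.17 ± 0.03) and SIG6 (0.08 ± 0.02) higher. Of these, PYK10 (−0.21, adjusted p = 0.0569) and P5CS1 (0.15, adjusted p = 0.061) did not pass without the library that lay apart. The sigma factor list had a median of 0.05 and a mean of −0.3, which SIG5 set, and an upward test (adjusted p = 0.44). For the morning clock genes the median was 0.01 and the test leaned down (adjusted p = 0.74), and members of the lists of cold transcription factors, raffinose, auxin and salicylic acid genes did not pass. In the single conditions other than 4 °C at ZT27, 7 lists were called at 19 °C at ZT27, 8 at 19 °C at ZT45 and 7 at 4 °C at ZT45, and none with an estimated correlation. They included the chlorophyll genes in each, with medians of 0.11, 0.19 and 0.06, and light-harvesting genes, with 0.15, 0.2 and 0.07. The smallest adjusted p in these with an estimated correlation was 0.075, for COR genes at 4 °C at ZT45 (median 0.18). Medians of lists matched to the light-harvesting genes for abundance centred on 0.08, 0.16 and 0.04 in the same order of conditions. They reached 0.14, 0.23 and 0.1, which at ZT45 is above the medians of the light-harvesting genes.

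**Figure D4:**
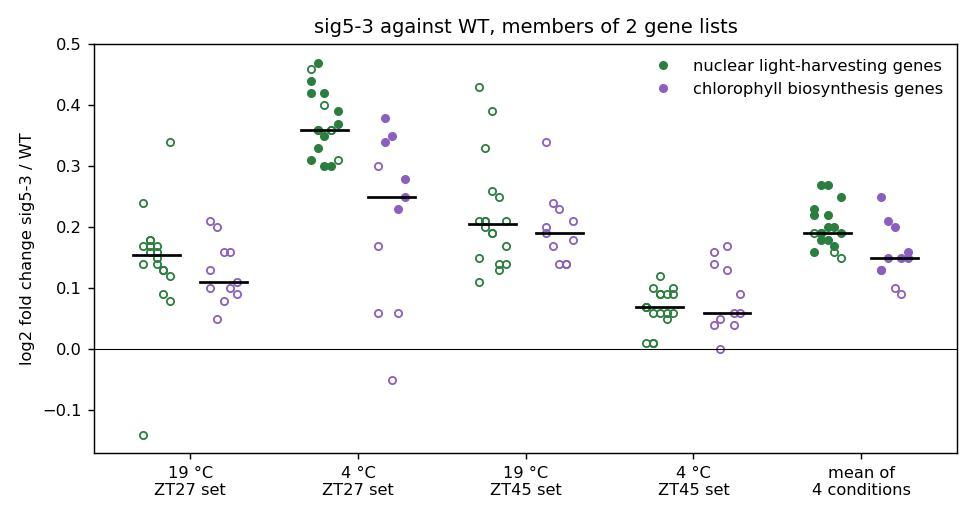
Log2 fold change (sig5-3 against WT) of nuclear light-harvesting and chlorophyll biosynthesis genes in each of the 4 conditions and averaged over them. Filled points passed at an adjusted p under 0.05, open points did not, and bars mark the median, 0.19 and 0.15 in the averages.

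Last, the 2 time sets were compared in WT. At 19 °C, the ZT45 set differed from the ZT27 set in time of day and in the hours spent in continuous light. The names give the start of the 3 h or 5 h of treatment and not the hour of sampling. LHY, a morning clock gene, was at 303 ± 17.8 (SD, n = 3) in the ZT45 set and 7.55 ± 1.48 in the ZT27 set (log2 difference 5.25 ± 0.12). FKF1, an evening gene, was at 0.685 ± 0.184 and 45.5 ± 4.84 (−5.28 ± 0.1). Among the 8 largest increases were the anthocyanin genes DFR (4.78 ± 0.23), LDOX (4.59 ± 0.19) and UF3GT (4.25 ± 0.17), the granule-bound starch synthase GBSS1 (4.35 ± 0.14), RVE8 (4.32 ± 0.14), ELIP2 (4.68 ± 0.2) and ELIP1 (4.11 ± 0.12). Among the decreases were AT1G56300 (−5.19 ± 0.1), AT2G33830 (−4.77 ± 0.17), COR27 (−4.74 ± 0.08), AT5G62360 (−4.6 ± 0.09), AT3G62550 (−4.57 ± 0.11), MEE14 (−4.51 ± 0.07) and PRR5 (−4.31 ± 0.1). SIG5 was 2.28 ± 0.19 higher (adjusted p = 3.7e-09). All 12 evening-phased genes were lower, 12 of them adjusted over the list alone (median −2.41, adjusted p = 7.3e-17, adjusted p = 0.00057 with an estimated correlation). All 12 flavonoid genes were higher (median 2.76, adjusted p = 3.1e-14, adjusted p = 0.029 with an estimated correlation). Of 15 COR genes 12 were lower and 1 higher (adjusted p = 9.1e-08, adjusted p = 0.08 with an estimated correlation). Of 13 starch degradation genes 8 were lower and 2 higher (adjusted p = 1e-04, adjusted p = 0.28 with an estimated correlation). Of 12 morning clock genes 9 were higher and 2 lower (adjusted p = 0.00018, adjusted p = 0.38 with an estimated correlation). Limma called 428 genes, 271 higher and 157 lower at ZT45, and 7435 passed without the fold threshold.

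The chilling response of WT differed between the time sets. The test of that difference called 285 genes, 49 with a higher and 236 with a lower response at ZT45, and 4716 passed without the fold threshold. SIG5 was among them, its response being lower at ZT45 (−1.67 ± 0.26, adjusted p = 7e-05). All 3 raffinose genes had a lower response at ZT45 (median −1.61, adjusted p = 5.9e-06, adjusted p = 0.049 with an estimated correlation). So did 10 of 15 COR genes, 11 adjusted over the list alone (median −1.38, adjusted p = 2.8e-11, adjusted p = 0.048 with an estimated correlation). Of 12 morning clock genes 9 did, 10 adjusted over the list alone (median −2.33, adjusted p = 4.5e-14, adjusted p = 0.084 with an estimated correlation). Light-harvesting genes also had a lower response at ZT45 in 15 of 18 cases, 18 adjusted over the list alone (median −0.88, adjusted p = 1.9e-13, adjusted p = 0.19 with an estimated correlation). Of 14 polymerase proteins 10 had a higher one, and adjusted over the list alone 12 a higher and 1 a lower one (median 0.38, adjusted p = 8e-06, adjusted p = 0.24 with an estimated correlation). LNK1 was the 1 gene called in opposite directions, at 1.91 ± 0.13 at ZT27 and −1.62 ± 0.13 at ZT45 (difference −3.53 ± 0.19, adjusted p = 6.3e-12). Across genes, the WT responses at the 2 times had a Pearson r of 0.735 and a Spearman rho of 0.651, with a slope of 0.454 of ZT45 on ZT27, and 185 genes were called at both, 114 up and 70 down. In sig5-3 these correlations were 0.721 and 0.632.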

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

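Tests chosen only after the results were seen were the corrections for transcript length and abundance, the test for WT plants at 4 °C at ZT45, the tests of light-harvesting genes without 1 library and against genes of like abundance, and the splits with mean effects removed.

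The chilling response of WT differed between the time sets in 285 genes by the test of the difference itself, limma's interaction term. The 5 largest differences each way were named by the rule for named genes, and the difference is the response at ZT45 minus that at ZT27. Responses were higher at ZT45 for AT3G62550 (3.71 ± 0.16, SE), the DnaJ-type gene AT5G23240 (2.77 ± 0.23), the germin-like gene GER3 (2.63 ± 0.17), CCL (2.43 ± 0.1) and MYC2, a jasmonate signalling factor (2.41 ± 0.78, adjusted p = 0.03). They were lower for AT4G06665 (−6.16 ± 1.54, adjusted p = 0.0065), ADH1 (−5.55 ± 0.17), GOLS3 (−4.68 ± 0.21), AT1G70640 (−3.95 ± 0.2) and LEA3, a late embryogenesis abundant protein gene (−3.84 ± 0.14), and SIG5 was at −1.67. AT4G06665 and MYC2 had residual SDs of 1.35 and 0.69, against a median of 0.12. Among 100 splits of the 12 WT libraries within temperature, 17 called as many genes as the real one, and the highest of the others called 970. Those splits mix the time sets within each temperature and so also read the difference between time sets, at 19 °C or at 4 °C. They do not isolate the difference of responses, and no conclusion about chance is drawn from them. With the mean effects of temperature and time removed, 1 of 100 splits, the real one, called as many, and the highest other called 97. That argues against chance as the source of all 285 calls. The test was chosen after the first result was seen, and it cannot give a share under 1 of 100. Start time and length of chilling differ together, so which of them sets these differences is open.

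SIG5 transcript left in sig5-3 was between 8.33% and 26.3% of the WT mean over the 12 libraries and rose with chilling. If WT plants in the samples were its source, AT3G06433, also low in sig5-3, would reach at least the same percentage. At 4 °C at ZT45 its highest percentage was 11.5, below the lowest SIG5 percentage of 18.4, which argues against WT plants as the whole source there. In 0 of the other 3 conditions did the percentages separate in this way, so in them WT plants and transcription from the insertion allele cannot be told apart, because the spreads of both genes overlap. Reads of another sigma factor gene are argued against, since the highest 4 °C to 19 °C ratio of the other 5 in sig5-3 at ZT27 was 1.86, for SIG1, against at least 8.48 for SIG5, and transcription from the insertion allele may account for the remainder but was not tested.

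Light-harvesting genes were higher in sig5-3 by a median of 0.19 averaged over the 4 conditions (list adjusted p = 3.1e-12, adjusted p = 0.2 with an estimated correlation), and in single conditions members passed only at 4 °C at ZT27. At 4 °C at ZT27 it may rest on replicate 1 of sig5-3, the library that lay apart: 1 of 18 genes passed without it, against 13 with it. Averaged over the 4 conditions 15 of 18 passed without it and 15 with it, which argues against that library as the whole source. An equal count does not show an equal effect, because leaving the library out also changed the shared error, and 1660 genes then passed against 1147. Sizes fell, for example from 0.27 to 0.23 for LHCB2.3 and from 0.27 to 0.21 for LHCB1.4. A trend with abundance stays open. The 18 genes exceeded the 100 genes nearest in mean value by 0.07 more in sig5-3 than in WT (exact permutation p = 0.039, two-sided, 160000 permutations within condition), but by 0.044 without that library (exact permutation p = 0.088), and the medians of 10000 lists matched for abundance centred on 0.12 and reached 0.18, against 0.19.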

How the results depend on the processing

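Alternatives chosen only after the data were seen were pseudocounts of 0.1 and 2, a minimum mean of 5, array weights and leaving out replicate 1 of sig5-3 at 4 °C at ZT27. Unless a cause is given, the cause was not tested. Calling by adjusted p alone drops the fold threshold and so raised the counts of called genes, to 10135 and 6396 for chilling in WT at ZT27 and ZT45, 10772 and 6330 in sig5-3, 7435 for the time sets at 19 °C, 4716 for their difference in chilling response, and for the genotypes to 1336 (4 °C at ZT27), 7 (19 °C at ZT45), 5 (4 °C at ZT45) and 1147 (mean of 4 conditions). With a pseudocount of 2, which shrinks folds of low genes, chilling at ZT45 called 137 genes in WT and 145 in sig5-3, and with 0.1 the genotypes at 4 °C at ZT27 gave 6. With only the groups compared in the fit, which leaves fewer samples to estimate the spread, the genotypes differed in 1 gene at 19 °C and 1 at 4 °C at ZT27. Array weights gave 6 genes between genotypes at 19 °C at ZT45 and 2 for the difference of responses at ZT27, and leaving out the sig5-3 library gave 5 and 1. The difference in SIG5 response between genotypes, not called in any of these fits, turned negative with a pseudocount of 2 (−0.371 at ZT27, −0.025 at ZT45) and, at ZT45, without sig5-3 replicate 3 at 4 °C (−0.035, the lowest of the leave-outs, which reached 0.218). Correlations between genotypes (0.956 at ZT27, 0.926 at ZT45) became 0.967 and 0.943 with a mean of at least 5, 0.967 and 0.934 with array weights, and 0.966 and 0.953 over genes passing in either response, and at ZT27 0.969 without the sig5-3 library. Those between times (0.735 in WT, 0.721 in sig5-3) became 0.745 and 0.74 with a mean of at least 5 and 0.751 and 0.738 over genes passing in either, 0.725 in WT with a pseudocount of 2, and in sig5-3 0.73 with array weights and 0.731 without that library. With a correlation estimated between genes, which widens the list test, the lists called in chilling fell from 10 to 1 (WT ZT27), 11 to 2 (WT ZT45), 11 to 1 (sig5-3 ZT27) and 11 to 4 (sig5-3 ZT45), and from 10 and 9 to 2 and 2 in the comparisons of time sets. In the genotype comparisons, where camera called 7, 8, 8 and 7 in single conditions and 10 on average, and 6 and 10 for the differences of responses, limma's camera called 0 lists with an estimated correlation, and 18 of these 133 list tests had an unadjusted p under 0.05. Fry, which asks another question, called 16 in WT at ZT27, 16 and 15 in the comparisons of time sets, 1 (19 °C ZT27), 7 (4 °C ZT27), 3 (19 °C ZT45), 1 (4 °C ZT45) and 10 (mean) between genotypes, and 4 and 0 for the differences of responses at ZT27 and ZT45. Leaving out each replicate gave 826 to 846 and 218 to 236 genes for chilling in WT at ZT27 and ZT45, 899 to 939 and 242 to 269 in sig5-3, 2 to 2, 2 to 11, 3 to 4 and 2 to 3 between genotypes (19 °C and 4 °C at ZT27, then at ZT45), 2 to 2 on average, 0 to 3 and 0 to 0 for the differences of responses, 273 to 303 for the difference between time sets and 421 to 445 at 19 °C. At 4 °C at ZT27 the counts beyond 1.5 times were 5 without WT replicate 2, 11 without sig5-3 replicate 2 and 7 without its replicate 3. Samples with the same replicate number had correlations of deviations averaging −0.028 at ZT27 and −0.074 at ZT45, so the numbers do not pair them, and with the number as a replicate block the counts in the same order were 833, 227, 899, 254, 2, 3, 4, 2, 2, 0, 0, 285 and 428. Among the values of single genes, those that had passed their threshold no longer did in 35 cases with only the groups compared, 23 without the sig5-3 library, 16 with the block, 13 with array weights, 10 with median-ratio scaling, 3 and 2 with pseudocounts of 2 and 0.1, and in 366 of the leave-outs, where 2735 stayed on their side of it. Median-ratio scaling moved the median of all genes by 0.031 or less upward and by −0.037 at most downward. A count model, a fit without a low-count filter and the removal and share of organelle transcripts were not run. Low genes are limited by depth, with 3 reads worth 0.0688 to 0.1115.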

Other observations

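Tests chosen only after the results were seen were the corrections of the library that lay apart for transcript length and abundance and the look at genes outside the lists and beside SIG5, all of them named after their values were seen.

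Outside the gene lists, small differences between genotypes passed at an adjusted p under 0.05 by limma in the average over the 4 conditions. Lower in sig5-3 were CYP81D11, a cytochrome P450 (−0.86 ± 0.07, SE, adjusted p = 5.2e-07), the glutathione transferase gene GSTU24 (−0.57 ± 0.12), the oxidoreductase gene ChlAKR (−0.63 ± 0.1) and the MATE-type efflux gene AT2G04050 (−0.9 ± 0.18). So were the lipid-transfer-type genes EARLI1 (−0.74 ± 0.1) and AT4G12490 (−0.74 ± 0.12), the receptor kinase gene IOS1 (−0.58 ± 0.12), the RPW8 homologue HR4 (−0.62 ± 0.16), BGLU11 (−0.64 ± 0.1) and AT2G18193 (−1.05 ± 0.2). Higher in sig5-3 were the Rubisco small subunit genes RBCS1B (0.29 ± 0.06) and RBCS2B (0.28 ± 0.05), near-identical copies whose shares of reads are uncertain, GER3 (0.27 ± 0.06) and the transcription factor gene TCP3 (0.27 ± 0.06). All 14 also passed without the library that lay apart, for example CYP81D11 at −0.87 (adjusted p = 2.9e-05). No rule for choosing the 14 was fixed beforehand. The larger increases of AT1G69140 (0.44), AT1G31690 (0.37) and AT1G60590 (0.3) and a decrease of AT4G01870 (−0.61) also passed with and without that library. RBCS1B and RBCS2B had mean values of 4280 and 4570, and a trend with abundance was not tested for them. Lists matched in abundance to the light-harvesting genes centred on 0.12 in this average. At 4 °C at ZT27 the anthocyanin genes AT5MAT (0.76), GSTF12 (0.69) and UF3GT (0.63) were higher in sig5-3. Without that library their sizes were similar (0.76, 0.63 and 0.59) but they did not pass (adjusted p = 0.056, 0.067 and 0.12). LDOX, a member of the flavonoid and anthocyanin list, was at 0.67 with that library. Without it LDOX was at 0.91 and passed (adjusted p = 0.022). Among the 6 measured genes on each side of SIG5, SQE6 (−0.33 ± 0.04, adjusted p = 0.00015) and SLAH3 (−0.31 ± 0.06, adjusted p = 0.0035) were lower, and beside AT3G06433 ATG8H was lower (−0.35 ± 0.1, adjusted p = 0.042) and PPR2 higher (0.11 ± 0.03, adjusted p = 0.023).

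The remaining lists called between the time sets of WT were the following. In the difference of chilling responses, ZT45 minus ZT27, 8 of 13 cold transcription factors were lower and 1 higher (median −0.78, adjusted p = 0.00018, adjusted p = 0.2 with an estimated correlation), and 8 of 12 flavonoid genes were lower (median −0.81, adjusted p = 5e-05, adjusted p = 0.19 with an estimated correlation). Of 11 HY5-associated genes 6 were lower and 2 higher (median −0.9, adjusted p = 0.00038, adjusted p = 0.089 with an estimated correlation). Of 12 evening-phased genes 6 were higher and 3 lower (adjusted p = 0.048, adjusted p = 0.27 with an estimated correlation), and of 13 starch degradation genes 6 were higher and 1 lower (adjusted p = 0.026, adjusted p = 0.53 with an estimated correlation). At 19 °C, 9 of 11 chlorophyll genes were higher at ZT45 and 1 lower (median 0.38, adjusted p = 0.00053, adjusted p = 0.25 with an estimated correlation), and 7 of 11 HY5-associated genes were higher and 2 lower (median 0.91, adjusted p = 0.0014, adjusted p = 0.13 with an estimated correlation). Of 10 auxin and growth genes 7 were lower (median −0.72, adjusted p = 0.0012, adjusted p = 0.22 with an estimated correlation), and of 14 polymerase proteins 9 were lower and 3 higher (median −0.28, adjusted p = 0.023, adjusted p = 0.53 with an estimated correlation).

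Replicate 1 of sig5-3 at 4 °C at ZT27 differed from the mean of the other libraries of its group by a root mean square of 0.394 on the log2 scale, against at most 0.187 in 21 libraries of other groups, and had an array weight of 0.087. Its COR, raffinose and abscisic acid lists had medians 0.33, 0.41 and 0.28 above the others of its group, beyond the ranges of those 21 libraries (−0.21 to 0.22, −0.25 to 0.15 and −0.14 to 0.11). The root mean square was 0.393 after the trend with transcript length was removed, 0.389 after the trend with abundance was removed, and 0.392 with the best-fitting admixture of another group (20% of WT at 4 °C at ZT27), which argues against each as the whole source. No biological explanation was tested, since the library has the labels of its group, and a difference in handling or in the plants stays open.

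Other splits of the samples were counted for each comparison. In the chilling comparisons, the genotype comparisons within 1 condition and the time sets at 19 °C, 1 of 10 splits of the 6 libraries, the real one, called as many genes, which is too few splits for a share under 0.05. The real counts were 833, 228, 899 and 257 for chilling (WT ZT27, WT ZT45, sig5-3 ZT27, sig5-3 ZT45), 2, 3, 3 and 2 for genotype (19 °C and 4 °C at ZT27, then at ZT45) and 428 for time, and the highest other split gave 0, or 1 for time. For the genotypes averaged over conditions, with labels redrawn within each temperature and time set, 1 of 100 splits, the real one, gave as many as 2 genes and the highest other 0. SIG5, the gene disrupted in this line, is 1 of those 2 genes. The real split was therefore bound to call more than the others, and no conclusion about chance is drawn for other genes. For the difference of responses between genotypes the real split gave 0 genes by limma (1782 with an unadjusted p under 0.05 at ZT27, 647 at ZT45). Any split gives at least 0, so the count of 100 of 100 was fixed beforehand and says nothing about chance. The highest other split gave 22 genes at ZT27 and 6 at ZT45.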
